A study of Mus musculus with 9 samples.

How the data were processed

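Polyadenylated RNA was sequenced from cultures of RAW264.7, a mouse macrophage-like cell line, in 3 groups of 3 libraries. The groups were an untreated blank control, cells on a membrane labelled BMC, and cells on the same membrane exposed to low-intensity pulsed ultrasound (BMC+LIPUS). Groups were taken from the sample labels, which do not say what BMC stands for. Per the labels' protocols, cells were grown in serum-containing αMEM medium, RNA was extracted with Trizol, and libraries were made with a stranded mRNA kit and sequenced as read pairs. Nothing in the labels says that the 3 libraries of a group came from separate cultures, so the p-values measure only the spread between these samples, which may be technical.

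Per the submitters' processing notes, reads were handled with cutadapt 1.9.1, HISAT2 2.0.1, HTSeq 0.6.1 and DESeq2 on the mouse build GRCm39. The version of DESeq2, the annotation, the strand setting of the counting and any filters are not given in the sources used here. The deposited table holds a read count and an FPKM value per gene and library. The deposited counts are whole numbers that were not normalized. The deposited FPKM values are fragments per kilobase, scaled to the total over all lines of the table, rounded by the authors to 2 decimals. The table has 56691 lines, of which 2639 carry no gene name. These unnamed lines held 0.0889% to 0.0976% of the counts of a library and were left out of library sizes and tests. A further 77 names stand on more than 1 line, and the line with the highest mean count kept the name. The table also has 6 columns of 3 other libraries, which no sample label names and which were not used here. Whether the labelled libraries of a group were selected from more is not known. The gene annotation at hand is of another build, so genes are given by symbol and no coordinates are printed. Because the strand setting is not given, reads of a gene and an antisense or overlapping partner cannot be told apart. Near-identical gene copies are also uncertain.

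Library sizes were the totals over named genes, 12675500 to 16574500 counts. The tests were first laid out for FPKM values with limma, with a written switch to count tests if the table held raw counts. It did, so edgeR 4.0.16 was the test for single genes and the FPKM fit became an alternative. Genes with a mean of at least 0.5 FPKM over the 9 libraries were tested, 12030 in all. TMM scaling factors, a quasi-likelihood fit (glmQLFit and glmQLFTest) of the 3 group means over all 9 libraries and Benjamini-Hochberg adjustment were used. A gene was called at an adjusted p under 0.05. Every adjusted p described as an edgeR value comes from this fit, or from the same fit without a library where the text says that it was left out. Fold changes are fitted values, and the standard error (SE) of a log2 change was derived from its F statistic. The median SE of a log2 change was 0.0952, 0.0963 and 0.0953 in BMC against control, BMC+LIPUS against BMC and BMC+LIPUS against control. Levels are mean FPKM ± SD (n = 3). A group with no counts for a gene was given a floor of 3 counts over the group's total. Such floors cover counting error only. There was no group with ultrasound and no membrane, so no interaction could be tested.

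Before the data were examined, 41 gene lists for macrophage polarization, inflammation, mechanical and calcium responses, metabolism, stress, cell cycle and other cell types were written down. Of their 1078 symbols, 1062 were found in the table, 14 of these through a RefSeq synonym. Lists with at least 5 tested genes were tested in each comparison with camera (limma 3.58.1) at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the 35 lists tested. The same test with an estimated correlation and fry, which tests whether the genes of a list move on balance one way, were run beside it. Counts of called members are given over all genes tested and adjusted over the list alone.

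The rule for named genes was also fixed before the data were examined. It takes Nos2, Tnf, Il1b, Il6, Cd86, Arg1, Mrc1, Il10, Cd163 and Piezo1 in each comparison. It adds the 6 largest rises and 6 largest falls in log2(FPKM + 1) among called genes whose groups do not overlap, leaving out predicted and clone names. It also adds up to 4 called members with the smallest p from each called list and from the 2 polarization lists, and up to 2 from other lists with at least 3 called members. Examples were taken from these genes. Called members that moved against the direction of their list are named as well, and these were chosen after their values were seen. Some single genes that these rules name are not reported here.

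The alternatives fixed in advance were limma on log2(FPKM + 1) and with a pseudocount of 0.1, no filter and a minimum of 5 FPKM, FPKM rescaled to 1 total, by median ratios or by quantiles, robust estimation, array weights, a fit of only the 6 libraries compared, replicate numbers as a block, a minimum absolute log2 change of 1, DESeq2 1.42.0, the other list tests, and leaving out each library. After seeing the data, RLE scaling factors, no scaling factors, and a score of osmotic stress genes as a covariate were added.

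The steps were tested on counts simulated from the real means, library sizes and gene-wise dispersions, with 50 genes changed at each of 4 fold sizes among 12030. For BMC against control, 34%, 78%, 90% and 98% of the genes changed 1.25, 1.5, 2 and 4 times were recovered. The shares were 28%, 78%, 80% and 98% for BMC+LIPUS against BMC, and 30%, 88%, 84% and 96% for BMC+LIPUS against control. Of the simulated calls, 9.09%, 8.39% and 7.45% were false in these comparisons. A list of 38 genes moved 1.25 times was called in each comparison, with 0, 2 and 0 other lists called beside it. With nothing changed, 0 genes and 0 lists were called by edgeR and camera in each simulated comparison. Genes were drawn independently of each other, so the simulations cannot show how often camera calls lists of correlated genes falsely. In the data, the estimated correlation was 0.60 for the ribosomal protein list in BMC against control. R 4.3.3, Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9 were used.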

Results

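RNA of RAW264.7 cells was counted per gene in 9 libraries, 3 each from the blank control, the BMC membrane and the BMC membrane with low-intensity pulsed ultrasound. The title of the series names ultrasound, piezoelectric membranes and macrophage polarization. The 3 control libraries held 14286100, 16574500 and 13691900 counts, the BMC libraries 13979900, 14682500 and 12831400, and the BMC+LIPUS libraries 15279300, 12675500 and 13720100, each rounded to 6 digits. Between 17073 and 17921 genes had at least 1 count in a library. Mitochondrial genes took 3.46% to 4.05% of the counts, and the most abundant gene, the ribosomal RNA-related Rn18s-rs5, took 1.63% to 1.91%. Pearson's r of log2 CPM between libraries, across genes that are not independent replicates, was 0.990 to 0.993 within groups and 0.988 to 0.993 between BMC and BMC+LIPUS. It was 0.976 to 0.983 between control and BMC, and 0.971 to 0.979 between control and BMC+LIPUS. No pair of libraries within a group was a near copy, since their counts differed by 3.54 to 10.0 times the sampling variance. The first principal component held 52.8% of the variance and placed the controls at -35.4 to -31.7, BMC at 6.16 to 17.96 and BMC+LIPUS at 14.5 to 26.7.

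The comparison of BMC with control asked what culture on the membrane does without ultrasound. On the membrane, chemokine transcripts rose and DNA replication transcripts fell. Cxcl2, a neutrophil-attracting chemokine, went from 4.72 ± 1.10 to 78.4 ± 5.78 FPKM (SD, n = 3), which was 17.5-fold higher (edgeR adjusted p = 2.74e-12). Ccl4 rose 8.04-fold and Ccl3 5.77-fold, while Acod1, the enzyme that makes itaconate, rose 13.1-fold to 84.8 ± 14.0 FPKM. The inflammatory cytokine Tnf rose 2.33-fold, from 49.0 ± 5.89 to 109 ± 9.67 FPKM (edgeR adjusted p = 5.85e-08). Uhrf1, which recruits DNA methyltransferase to replicating DNA, was 3.32-fold lower, falling from 72.6 ± 3.53 to 20.9 ± 2.73 FPKM (edgeR adjusted p = 4.20e-09).

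Among called genes whose groups do not overlap, leaving out predicted and clone names, the largest rises in log2(FPKM + 1) also included Clec4n, a fungal pattern receptor also known as Dectin-2, at 6.95-fold, and the transcription factor Egr2, at 5.79-fold. The largest falls on that scale, beside Uhrf1, included S1pr1, a sphingosine-1-phosphate receptor, at 3.48-fold lower, and Odf3l1 at 3.27-fold lower. Ung, a uracil-DNA glycosylase, was 3.13-fold lower, the replication fork gene Timeless 2.98-fold lower, and the replication licensing gene Cdc6 2.89-fold lower.

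**Figure D1:**
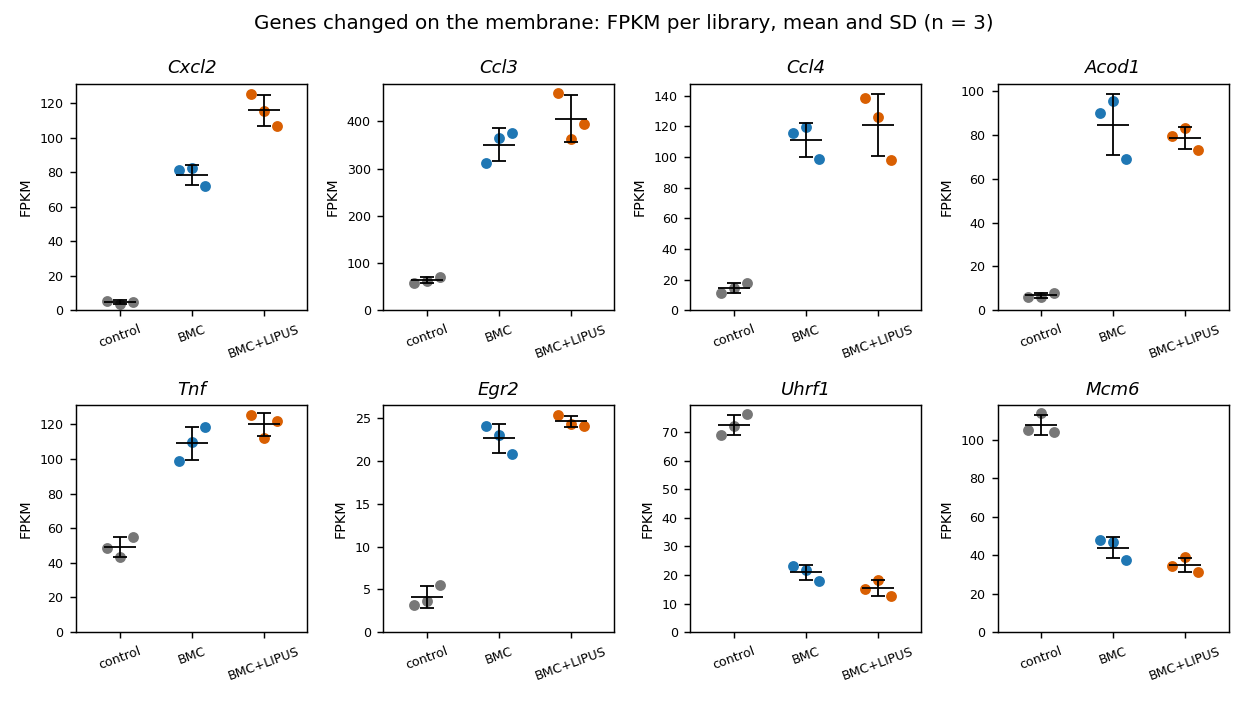
FPKM of 8 genes in each of the 9 libraries (points) by group, with the group mean and SD (n = 3) as bars. Cxcl2, Ccl3, Ccl4, Acod1, Tnf and Egr2 are higher and Uhrf1 and Mcm6 are lower in both membrane groups than in control, with Mcm6 at 108, 43.9 and 34.9 FPKM in control, BMC and BMC+LIPUS.

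Of the 41 lists, 35 could be tested, and camera called 17 of them in BMC against control, 14 higher and 3 lower. Of these, 6 held with an estimated correlation. All 38 DNA replication genes fell, also when adjusted over the list alone, with a median log2 change of -1.07 (camera adjusted p = 8.18e-63, and adjusted p = 0.0207 with an estimated correlation). Examples are the helicase subunits Mcm6, 2.34-fold lower, and Mcm7, 2.10-fold lower, and the maintenance methyltransferase Dnmt1, which fell from 74.0 ± 1.83 to 29.2 ± 1.27 FPKM. In the chemokine list 5 of 7 tested genes rose and 0 fell by edgeR, and 5 rose and 1 fell adjusted over the list alone. Its median log2 change was 1.18 (camera adjusted p = 2.59e-22, and adjusted p = 0.0151 with an estimated correlation), and it includes Cxcl14, 2.27-fold higher. In the NF-kB pathway and feedback list 20 of 22 rose, also adjusted over the list alone (median 0.53, camera adjusted p = 2.79e-12, and adjusted p = 0.0274 with an estimated correlation). Traf1, a signalling adaptor, rose 3.40-fold, and the atypical inhibitor Nfkbiz rose 2.35-fold. The adhesion molecule Icam1 and the subunit Nfkb2 each rose 1.65-fold.

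Of 25 immediate early and MAPK feedback genes 17 rose and 1 fell, and 19 rose and 1 fell adjusted over the list alone (median 0.58, camera adjusted p = 2.21e-07, and adjusted p = 0.0274 with an estimated correlation). Ier3 rose 5.13-fold, from 19.1 ± 3.88 to 93.4 ± 35.9 FPKM, and the mRNA-destabilizing protein gene Zfp36 rose 2.11-fold. Ier2 rose 1.78-fold and Junb 1.49-fold. The member that fell was Fos, an AP-1 subunit, which was 1.95-fold lower. Of 27 amino acid and ATF4 stress genes 20 rose and 0 fell by edgeR, and 21 rose and 1 fell adjusted over the list alone (median 0.43, camera adjusted p = 2.20e-09, and adjusted p = 0.0274 with an estimated correlation). The transcription factor Atf4 rose 1.60-fold, the glutathione-degrading enzyme Chac1 4.75-fold, the glutamine transporter Slc1a5 1.49-fold, and asparagine synthetase Asns by 0.58 log2. Of 11 extracellular matrix and matrix-degrading genes 7 rose and 2 fell, and 7 rose and 3 fell adjusted over the list alone (median 0.42, camera adjusted p = 3.38e-06, and adjusted p = 0.0238 with an estimated correlation). The heparan sulfate proteoglycan Sdc4 rose 3.43-fold, the urokinase receptor Plaur 2.33-fold and osteopontin (Spp1) 1.99-fold. The 2 that fell were Sdc1, another syndecan, at 2.22-fold lower, and galectin-3 (Lgals3), at 1.14-fold lower. The matrix list was called by camera with 5 of 6 other scalings, and its median ran from 0 to 0.44 over 24 settings. That of the chemokine list ran from 1.02 to 1.82 and that of the ATF4 list from 0.28 to 0.45.

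Both polarization lists had more members that rose than fell on the membrane, and both also had members that fell. Of the 16 tested pro-inflammatory (M1) genes 8 rose and 4 fell, also adjusted over the list alone, with a median of 0.35 (camera adjusted p = 2.80e-07, but adjusted p = 0.0585 with an estimated correlation). Besides Acod1 and Tnf, the prostaglandin synthase Ptgs2 rose 5.28-fold to 4.06 ± 0.491 FPKM. The costimulatory ligands Cd80 and Cd86 rose 3.93-fold and 3.03-fold, Cd86 from 0.350 ± 0.147 to 1.00 ± 0.347 FPKM (edgeR adjusted p = 0.000717). The members that fell included the interferon-response factor Irf1, at 1.62-fold lower, the cytokine-signalling inhibitor Socs3, at 1.63-fold lower, and the IgG receptor Fcgr1, at 1.15-fold lower. Of the 14 tested alternative (M2) genes 6 rose and 2 fell, and 7 rose and 2 fell adjusted over the list alone, with a median of 0.36 (camera adjusted p = 0.00380, but adjusted p = 0.436 with an estimated correlation). Egr2 rose as given above, the histone demethylase Kdm6b rose 2.61-fold, and the interleukin-1 receptor antagonist Il1rn rose 2.67-fold. Klf4, a transcription factor, was 2.84-fold lower, and the lipid receptor Trem2 fell by 0.58 log2. The M1 median was 0.23 without BMC replicate 2 and 0.14 with no filter, and the M2 median was 0.08 without BMC replicate 1 and 0.74 with the osmotic score described below as a covariate. The M2 list was called with 4 of 6 other scalings.

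Several usual polarization markers were near the detection floor. Nos2, the inducible nitric oxide synthase, had 0, 2 and 1 counts in all control, BMC and BMC+LIPUS libraries together. Il6 and Cd163 had 0 counts in each group, which allows up to 0.0673, 0.0723 and 0.0720 CPM in control, BMC and BMC+LIPUS. Arginase (Arg1) stood at 0.010, 0.060 and 0.107 FPKM in the same order, the mannose receptor Mrc1 at 0.170, 0.103 and 0.0867, and Il10 at 0.0167, 0.0533 and 0.127, all below the filter. Il1b, at 0.557 ± 0.0757 in control and 0.417 ± 0.220 FPKM in BMC, was not called (log2 change -0.31, SE 0.39, edgeR adjusted p = 0.576). Neither was the mechanically gated channel gene Piezo1, at 7.87 ± 0.216 and 7.86 ± 0.474 FPKM (log2 change 0.06, SE 0.07, edgeR adjusted p = 0.554).

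The other 9 lists called in BMC against control lost the call with an estimated correlation. Of 31 G2/M cell cycle genes 19 fell and 0 rose by edgeR, 20 fell adjusted over the list alone, and the median was -0.28 (camera adjusted p = 2.88e-06, and adjusted p = 0.306 with an estimated correlation). The spindle checkpoint kinase Bub1b was 1.57-fold lower and topoisomerase Top2a 1.48-fold lower. Of 23 glycolysis genes 14 rose and 4 fell, also adjusted over the list alone (median 0.28, camera adjusted p = 0.00313, and adjusted p = 0.435 with an estimated correlation). Phosphofructokinase Pfkp rose 1.89-fold and the glucose transporter Slc2a1 1.88-fold, while the isoform Pfkm was 1.83-fold lower Hk3 and Pdk1 were 1.44-fold and 1.13-fold lower, and Slc2a3 fell by 0.33 log2. Of 19 hypoxia target genes 10 rose and 2 fell, and 10 rose and 3 fell adjusted over the list alone (median 0.21, camera adjusted p = 0.0265, and adjusted p = 0.197 with an estimated correlation). Ddit4, an inhibitor of mTORC1, rose 2.33-fold and the repressor Bhlhe40 2.20-fold, and the members that fell were Ndrg1, at 2.08-fold lower, and Selenbp1, at 2.06-fold lower. Of 17 heat shock genes 12 rose and 0 fell by edgeR, and 13 rose and 1 fell adjusted over the list alone (median 0.21, camera adjusted p = 0.0114, and adjusted p = 0.542 with an estimated correlation). Chordc1 rose 1.36-fold. Hspa1b, whose near-identical copy Hspa1a makes its counts uncertain, was fitted 6.26-fold higher with a log2 SE of 0.51.

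Of 30 ribosome biogenesis and MYC target genes 16 rose and 1 fell, and 18 rose and 1 fell adjusted over the list alone (median 0.17, camera adjusted p = 0.00368, and adjusted p = 0.542 with an estimated correlation). Ornithine decarboxylase (Odc1) rose 1.34-fold, and Cad, of pyrimidine synthesis, was 1.32-fold lower. Of 42 ribosomal protein genes, whose pseudogenes make them uncertain, 11 rose and 0 fell by edgeR, and 2 rose adjusted over the list alone (median 0.16, camera adjusted p = 0.00598, and adjusted p = 0.692 with an estimated correlation). Rpl27 rose 1.35-fold. Of 24 LXR and lipid handling genes 2 rose and 9 fell, and 3 rose and 10 fell adjusted over the list alone (median -0.16, camera adjusted p = 0.0457, and adjusted p = 0.240 with an estimated correlation). The lysosomal cholesterol transporter Npc1 was 1.61-fold lower and the acid lipase Lipa 1.36-fold lower, while the cholesterol exporter Abca1 rose 1.37-fold and Npc2 1.13-fold. Of 25 p53 target and apoptosis genes 10 rose and 5 fell, also adjusted over the list alone (median 0.07, camera adjusted p = 0.0336, and adjusted p = 0.435 with an estimated correlation). The cell cycle inhibitor Cdkn1a rose 1.73-fold and the survival gene Mcl1 1.49-fold, and the members that fell included Phlda3, Trp53inp1 and Bcl2l11, at 1.64-fold, 1.52-fold and 1.22-fold lower. Of 24 phagocytic and complement receptors 9 rose and 6 fell, and 9 rose and 7 fell adjusted over the list alone (camera adjusted p = 0.00837, and adjusted p = 0.435 with an estimated correlation). This list was called higher and its mean was 0.24, but its median was -0.04 and ran from -0.15 to 0.25 over 24 settings. The complement receptor C5ar1 rose 4.05-fold and Clec4e 2.97-fold, while Stab1, C3ar1, Cd33, Lrp1, Scarb1 and Sirpa were 2.31-fold, 1.92-fold, 1.79-fold, 1.48-fold, 1.35-fold and 1.17-fold lower. With the 6 other scalings, none of these lists turned direction in camera, but the p53 list was called in 2 (its median changed sign in 1), the phagocytic list in 2, the hypoxia list in 4, and the heat shock, ribosomal protein and ribosome biogenesis lists in 5. Over 24 settings the medians ran from 0.15 to 0.31 for glycolysis, 0.11 to 0.25 for hypoxia, 0.11 to 0.23 for heat shock, 0.024 to 0.19 for ribosomal proteins, 0.070 to 0.18 for ribosome biogenesis and -0.011 to 0.12 for p53.

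In all, edgeR called 4314 of 12030 genes between BMC and control, 2062 higher and 2252 lower, and 423 of them differed at least 2-fold. The median absolute log2 change of the called genes was 0.41. The 3 libraries of each group did not overlap in 5588 of the 12030 genes, against 10% that chance gives, and in 4017 of those called. The split of higher and lower calls moved with the scaling: it was 1457 higher and 2761 lower with library totals, 1330 and 2545 with limma on log2(FPKM + 1), and 1100 and 2684 with FPKM rescaled to 1 total.

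The mean log2 CPM of Slc5a3, Akr1b3, Slc6a12 and Hspa4l, an osmotic score of genes chosen after seeing the data, was 6.77, 6.45 and 6.66 in the controls, 6.91, 7.53 and 8.27 in BMC and 8.11, 7.30 and 8.68 in BMC+LIPUS. Among the BMC libraries the mean log2 CPM of the heat shock, phagocytic and M2 lists had SDs of 0.143, 0.207 and 0.272. By edgeR, Slc5a3 was not called in BMC against control (adjusted p = 0.0666), and none of the 4 was called in BMC+LIPUS against BMC. With this score as a covariate, edgeR called 3056 genes in BMC against control and 2808 in BMC+LIPUS against control. Markers of other cell types were few above the filter. Of the fibroblast, stromal and osteoblast markers, Pdgfrb was above it and rose 2.06-fold on the membrane, from 0.610 to 1.21 FPKM. Of the lymphocyte markers, Lck rose 2.72-fold, from 0.860 to 2.22 FPKM, and Ighm fell from 134 to 91.3 FPKM (log2 change -0.49). Of the dendritic cell markers, Cd83, a maturation marker, rose 2.57-fold, from 12.8 to 31.4 FPKM, Siglech fell by 1.04 log2, and Bst1 and Tcf4 were not called. The granulocyte and mast cell markers S100a8 and Cebpe and, of the epithelial and endothelial markers, Eng were not called.

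By the labels, BMC+LIPUS and BMC, compared next, differed in ultrasound. Few genes were called, and each called gene changed by less than 2-fold. Rcan1, a calcineurin regulator that is itself induced by calcineurin signalling, rose 1.42-fold from 43.9 ± 1.30 to 62.1 ± 3.71 FPKM (n = 3, edgeR adjusted p = 0.00392), with control at 12.5 ± 0.670. Cxcl2 rose a further 1.48-fold, from 78.4 ± 5.78 to 116 ± 9.13 FPKM (edgeR adjusted p = 0.0341). S1pr2, a sphingosine-1-phosphate receptor, was 1.47-fold lower, falling from 5.65 ± 0.423 to 3.84 ± 0.467 FPKM (edgeR adjusted p = 0.0196). The polarization genes Tnf (log2 change 0.15, edgeR adjusted p = 0.556), Cd86 (0.42, edgeR adjusted p = 0.556) and Il1b (1.29, edgeR adjusted p = 0.182) were not called, nor was Piezo1 (0.18, edgeR adjusted p = 0.366).

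EdgeR called 13 genes here, 11 higher and 2 lower. The other named genes that rose were Abi3, at 1.69-fold, the autophagy gene Uvrag, at 1.55-fold, and the kinase gene Plk3 and Osgin2, each at 1.49-fold. Lhfpl2 was 1.29-fold lower. Among the remaining 5, named after their values were seen, Cep250, Malat1, Mmd and Fyn rose 1.46-fold, 1.39-fold, 1.32-fold and 1.28-fold. Of the 13, 12 were also called in the same direction in BMC against control, the exception being Abi3 (edgeR adjusted p = 0.150). At an unadjusted p under 0.05 there were 1384 genes, and the groups did not overlap in 1899 of 12030 genes, against 10% that chance gives. The calls held in 19 of 24 settings tried for Rcan1, 15 for Osgin2, 13 for Cxcl2, S1pr2 and Cep250, 10 for Malat1 and Mmd, 9 for Fyn, 8 for Plk3 and Uvrag and 7 for Lhfpl2, and in 8 of 23 for Abi3. The count depended on single libraries: 7, 6 and 4 without control replicates 1, 2 and 3, 3, 2 and 51 without BMC replicates 1, 2 and 3, and 0 and 2 without BMC+LIPUS replicates 1 and 3. DESeq2 called 88 genes (48 higher, 40 lower), and limma on FPKM rescaled to 1 total called 1 gene.

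**Figure D2:**
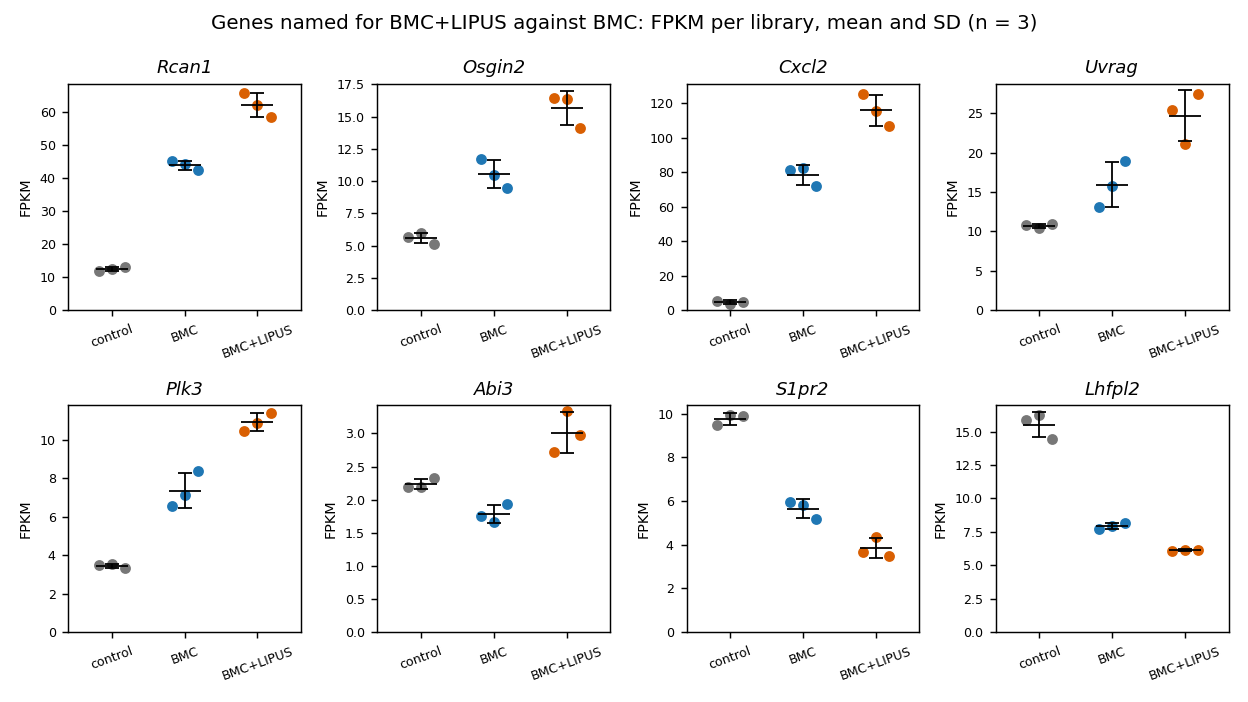
FPKM of the 8 genes named for BMC+LIPUS against BMC in each of the 9 libraries (points), with the group mean and SD (n = 3) as bars. The BMC and BMC+LIPUS libraries do not overlap in any of the 8, and Rcan1 stands at 12.5, 43.9 and 62.1 FPKM in control, BMC and BMC+LIPUS.

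Camera called 5 lists in BMC+LIPUS against BMC, 3 higher and 2 lower, all with small medians. For DNA replication genes edgeR called 0 of 38 members over all genes and 21, all lower, adjusted over the list alone, with a median of -0.22 (camera adjusted p = 6.87e-24, but adjusted p = 0.433 with an estimated correlation). The other lists with 0 called members over all genes were the immediate early genes (5 higher adjusted over the list alone, median 0.14, camera adjusted p = 0.00170), the nuclear oxidative phosphorylation genes (0 adjusted over the list alone, median -0.06, camera adjusted p = 0.00259), the integrins and focal adhesion genes (1 higher adjusted over the list alone, median 0.08, camera adjusted p = 0.0136) and the mechanosensitive and calcium channels (2 higher adjusted over the list alone, median 0.13, camera adjusted p = 0.0245). With an estimated correlation the immediate early list had an adjusted p = 0.433 and the other 3 an adjusted p = 0.751. With an estimated correlation, camera called 0 lists, with 2 at an unadjusted p under 0.05, and fry called 0, with 4 at that level. The channel list was called with 3 of 6 other scalings. Over 24 settings its median ran from 0.030 to 0.17, that of the integrin list from 0.013 to 0.15 and that of the oxidative phosphorylation list from -0.11 to -0.034. The DNA replication median ran from -0.28 to -0.17 and the immediate early median from 0.10 to 0.18. At the preset correlation, camera called the DNA replication list in 24 of these settings and the immediate early list in 23. It called the oxidative phosphorylation, integrin and channel lists in 21, 20 and 14. The M1 list (median 0.02, 0 members called and 3 higher adjusted over the list alone) and the M2 list (median 0.09, 0 called, with 1 higher and 1 lower adjusted over the list alone) were not called, both at a camera adjusted p = 0.341. The M1 median was below 0 in 7 other settings, at -0.093 to -0.016, and when any of BMC replicates 1 and 3 and BMC+LIPUS replicates 1 and 3 was left out. With the osmotic score as a covariate the M2 list was called (median 0.20, camera adjusted p = 0.000105). Without BMC replicate 1, 10 lists were called, among them the M2 list (median 0.21, camera adjusted p = 0.00736), and without BMC replicate 3, 2 were.

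**Figure D3:**
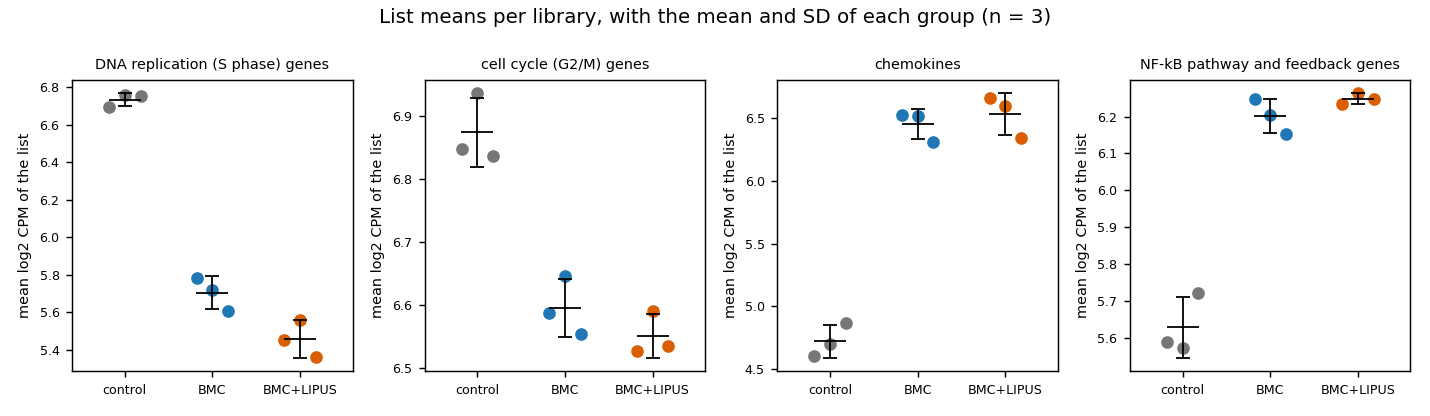
Mean log2 CPM over the tested members of 4 gene lists in each of the 9 libraries (points), with the group mean and SD (n = 3) as bars and a vertical axis that does not start at 0. The DNA replication genes stand at 6.73, 5.70 and 5.46 in control, BMC and BMC+LIPUS, and the chemokines at 4.72, 6.45 and 6.53.

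The comparison of BMC+LIPUS with control combines membrane and ultrasound. Chemokines again rose and replication genes again fell. Cxcl2 was 25.9-fold higher than in control, Acod1 12.2-fold and Ccl4 8.76-fold (edgeR adjusted p = 3.88e-13, 5.63e-12 and 2.89e-10). Clec4n rose 8.89-fold, Ier3 8.35-fold and Ccl3 6.69-fold. Calhm6 was 15.4-fold lower, falling from 3.63 ± 0.587 to 0.217 ± 0.145 FPKM (n = 3, edgeR adjusted p = 9.02e-07), and Klf4, Odf3l1, Uhrf1, Ung and Cdc6 were 4.62-fold, 4.54-fold, 4.52-fold, 4.33-fold and 4.16-fold lower.

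Camera called 14 lists, 12 higher and 2 lower, and 6 held with an estimated correlation. All 38 DNA replication genes fell, also adjusted over the list alone (median -1.28, camera adjusted p = 3.66e-70, and adjusted p = 0.0175 with an estimated correlation). The chemokine list had 5 members that rose and 1 that fell of 7, also adjusted over the list alone (median 1.18, adjusted p = 0.0175 with an estimated correlation by camera). The member that fell was Cxcl16, at 1.21-fold lower. In the NF-kB list 18 of 22 rose, and 19 adjusted over the list alone (median 0.54, adjusted p = 0.0338 with an estimated correlation by camera), with Nfkbiz 2.85-fold higher. Of 25 immediate early genes 20 rose and 1 fell, also adjusted over the list alone (median 0.80, adjusted p = 0.0301 with an estimated correlation by camera). Fos was again the member that fell, from 39.6 ± 2.59 to 15.1 ± 3.24 FPKM, which is 2.51-fold lower, while Fosl2, of the same family, rose 2.23-fold. Of 27 amino acid and ATF4 stress genes 21 rose and Cebpg fell, also adjusted over the list alone (median 0.43, adjusted p = 0.0338 with an estimated correlation by camera), with the stress sensor Sesn2 2.14-fold higher. Of 11 matrix genes 6 rose and 2 fell, also adjusted over the list alone (median 0.30, adjusted p = 0.0301 with an estimated correlation by camera), but this list was called with 4 of 6 other scalings, and its median ran from 0.12 to 0.60 over 24 settings, as that of the chemokine list did from 1.02 to 1.93.

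Of the M1 genes 9 rose and 4 fell of 16, also adjusted over the list alone (median 0.51, camera adjusted p = 1.95e-06, but adjusted p = 0.0781 with an estimated correlation). Tnf rose 2.57-fold to 120 ± 6.81 FPKM (edgeR adjusted p = 8.79e-09), Cd86 4.07-fold to 1.34 ± 0.0321 FPKM, Cd80 5.66-fold and Ptgs2 7.73-fold, and the members that fell included Irf1, Socs3 and Fcgr1, at 2.07-fold, 1.95-fold and 1.23-fold lower. Of the M2 genes 7 rose and 3 fell of 14, also adjusted over the list alone (median 0.41, camera adjusted p = 0.00469, but adjusted p = 0.462 with an estimated correlation). Egr2 rose 6.33-fold, Il1rn 3.64-fold and Kdm6b 3.28-fold, and with Klf4 the members Trem2 and Msr1 were lower, at 1.65-fold and 1.24-fold. Il1b was 1.98-fold higher at 1.05 ± 0.203 FPKM (edgeR adjusted p = 0.0277), a call lost without control replicate 1 or 2 (edgeR adjusted p = 0.0573 and 0.0978) or without BMC+LIPUS replicate 2 or 3 (0.0923 and 0.0527). The call of Il1b held in 16 of 23 settings tried. Piezo1 was 1.19-fold higher at 8.90 ± 0.816 FPKM (edgeR adjusted p = 0.0137), a call lost without control replicate 1 (edgeR adjusted p = 0.0558) or without BMC+LIPUS replicate 2 or 3 (0.0502 and 0.0614). It held in 14 of 24 settings tried. The M2 list was called with 4 of 6 other scalings and not at a minimum of 5 FPKM (median 0.37, camera adjusted p = 0.0577), and its median was 1.21 with the osmotic score as a covariate. The M1 median was 0.15 at a minimum of 5 FPKM.

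The other 6 called lists lost the call with an estimated correlation. The G2/M list had 22 of 31 members lower, also adjusted over the list alone (median -0.30, adjusted p = 0.332 with an estimated correlation by camera), with Ccna2 1.58-fold lower. Of 23 glycolysis genes 14 rose and 4 fell, and 15 rose and 4 fell adjusted over the list alone (median 0.28, adjusted p = 0.376 with an estimated correlation by camera), with Pfkp 2.28-fold higher. Of 17 heat shock genes 11 rose and 1, Dnajb1, fell, also adjusted over the list alone (median 0.22, adjusted p = 0.546 with an estimated correlation by camera), with Bag3 higher by 0.48 log2. Of 42 ribosomal protein genes 5 rose, also adjusted over the list alone (median 0.13, adjusted p = 0.741 with an estimated correlation by camera). Of 30 ribosome biogenesis genes 16 rose and 2, Cad and Nolc1, fell, and 17 rose and 2 fell adjusted over the list alone (median 0.17, adjusted p = 0.536 with an estimated correlation by camera). Of 24 phagocytic and complement receptors 9 rose and 7 fell, and 10 rose and 7 fell adjusted over the list alone (median -0.08, mean 0.27 and called higher, adjusted p = 0.462 with an estimated correlation by camera), with C1qa, at 2.79-fold lower, joining those that fell in BMC. With the 6 other scalings the phagocytic list was called in 2, the ribosomal protein list in 4 and the heat shock list in 5. Over 24 settings their medians ran from -0.18 to 0.32, 0.016 to 0.17 and 0.11 to 0.25, and that of ribosome biogenesis from 0.082 to 0.20. All 14 lists were also called in the same direction in BMC against control. The hypoxia, p53 and LXR lists were called there and not here, and the differences were not tested.

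**Figure D4:**
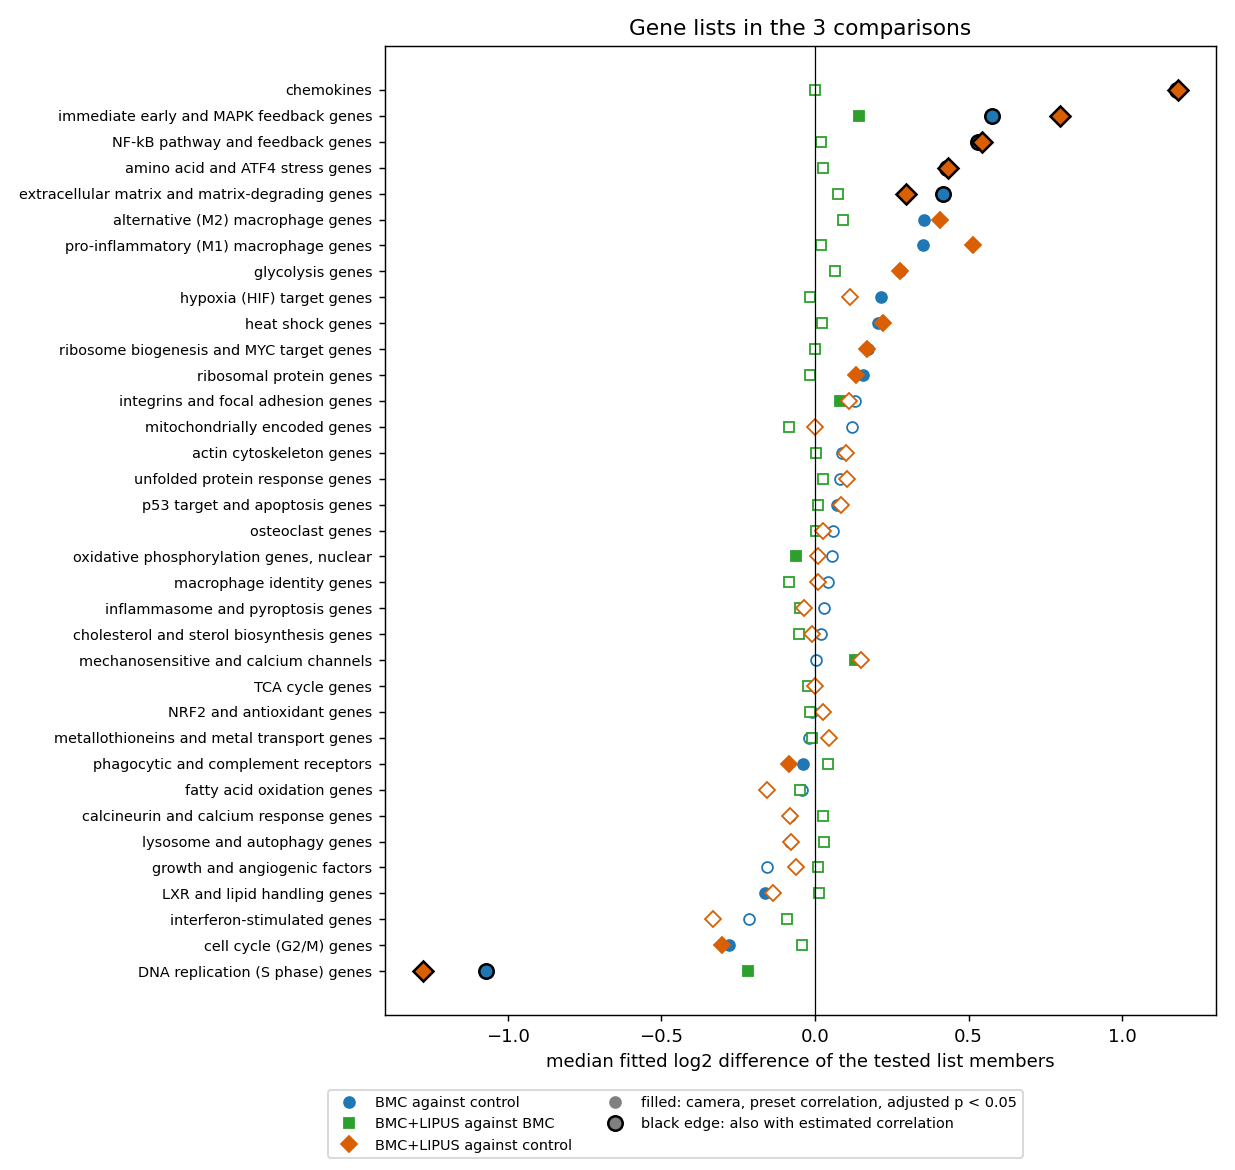
Median fitted log2 difference of the tested members of 35 gene lists (horizontal axis) in the 3 comparisons, with filled symbols for lists called by camera at the preset correlation and black edges for those also called with an estimated correlation. The DNA replication list lies at -1.07, -0.22 and -1.28 in BMC against control, BMC+LIPUS against BMC and BMC+LIPUS against control, and the p53 median changes sign in BMC against control under 1 of 6 other scalings.

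In all, edgeR called 5157 genes between BMC+LIPUS and control, 2525 higher and 2632 lower, of which 662 differed at least 2-fold. The libraries did not overlap in 6120 of 12030 genes, against 10% that chance gives. The split was 1868 higher and 3205 lower with library totals, 1735 and 3030 with limma on log2(FPKM + 1), and 1596 and 3034 with FPKM rescaled to 1 total. Over the 3 groups an edgeR F test called 4919 genes.

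Of the genes called against control, 1792 were higher and 2004 lower in both membrane groups, 3796 in all. Independent lists of these sizes would share 433 and 493. Unchanged groups simulated with shared controls had a mean of 0.15 such genes in 20 simulations. So few genes are called when nothing changes that this count gives no baseline for groups that differ. With 3 control libraries the controls could not be divided into parts of at least 2, so part of the excess of shared calls may come from the shared controls. The covariance of the fitted log2 changes was 0.232, against 0.0318 in the simulations, a difference of 0.201, and Pearson's r across genes was 0.830 against 0.490. Of the genes called in BMC against control, 10 rose and 2 fell further in BMC+LIPUS against BMC, and edgeR called 0 genes in opposite directions, while DESeq2 called 4. Unchanged groups simulated with BMC libraries shared by both comparisons gave 0 genes called the same way and 0 called opposite ways. Since few genes are called when nothing changes, these counts give no baseline for groups that differ. Independent lists, which leave out that the comparisons share these libraries with opposite sign, would give 1.89 higher in both, 0.374 lower in both and 2.4 opposite. At an unadjusted p under 0.05 the comparisons held 5366 and 1384 genes.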

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

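The RLE scaling factors, the fits without scaling factors and those with the osmotic score as a covariate were chosen after seeing the data. Most results against control held: over the settings other than a minimum change and the leaving out of libraries, genes changed ran from 2974 to 4700 in BMC against control and from 2808 (osmotic score) to 5493 in BMC+LIPUS against control. A minimum absolute log2 change of 1 left 423 and 662 genes, 671 in the test of the 3 groups, 376 called the same way in both membrane groups and 0 in BMC+LIPUS against BMC. With the osmotic score, 3015 genes differed among the 3 groups, 2317 went the same way in both membrane groups and 9 were called in BMC against control and the opposite way in BMC+LIPUS against BMC. That last count was 0 with edgeR, 21 with no filter, 2 with robust estimation, 4 with the replicate block, 2 with the block by description number and 4 with DESeq2. The 13 genes changed in BMC+LIPUS against BMC became 0 with limma on log2(FPKM + 1), 1 with a pseudocount of 0.1, 234 with no filter, 8 at 5 FPKM, 1 with FPKM rescaled to 1 total, 0 with median ratios, 1 with quantiles, 40 with robust estimation, 0 with array weights, 2 with only the 6 libraries compared, 53 with the replicate block, 52 with the block by description number, 88 with DESeq2 and 220 with the osmotic score. Deviations of libraries sharing a number were not correlated above 0.1 throughout. Between BMC and BMC+LIPUS, replicates 1, 2 and 3 had r = -0.035, 0.030 and 0.21. BMC replicate 1 and BMC+LIPUS replicate 2, which share no number, had r = 0.23. The 0.21 therefore does not show that the numbers pair libraries, and whether they do was left open. The 5 lists called there became 3 with no filter, 3 at 5 FPKM, 3 with array weights, 0 with an estimated correlation, 0 with fry and 11 with the osmotic score. Against control, the lists called became 9 (quantiles) and 6 (estimated correlation) in BMC, and 6 (estimated correlation) and 25 (fry) in BMC+LIPUS.

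The M1 median in BMC+LIPUS against BMC, 0.02 and not called, turned to -0.029 with limma on log2(FPKM + 1), -0.057 with a pseudocount of 0.1, -0.093 at 5 FPKM, -0.017 with FPKM rescaled to 1 total, -0.027 with median ratios, -0.016 with quantiles and -0.016 with the osmotic score. The M2 median there was -0.054 at 5 FPKM and 0.20 with the osmotic score, where camera called it. The M2 call in BMC against control was lost with median ratios (0.27), quantiles (0.26) and an estimated correlation (0.36). In BMC+LIPUS against control it was lost at 5 FPKM (0.37), with median ratios (0.33), with quantiles (0.33) and with an estimated correlation (0.41). Against control the M2 median rose to 0.74 in BMC and 1.21 in BMC+LIPUS with the osmotic score, and with all libraries kept its lowest values were 0.19 with FPKM rescaled to 1 total and 0.24 with array weights. The M1 median fell to 0.14 in BMC with no filter and to 0.15 in BMC+LIPUS at 5 FPKM, and stayed called in both. The M1 call was lost with an estimated correlation in BMC (0.35) and in BMC+LIPUS (0.51), each against control. Piezo1 in BMC against control, not called, turned to -0.0027 with limma on log2(FPKM + 1), -0.0031 with a pseudocount of 0.1, -0.025 with FPKM rescaled to 1 total and -0.0018 with library totals. Of 109, 13 and 103 called named genes in the 3 comparisons, 103, 0 and 95 kept the call in all 24 settings, and 0 changed direction. Leaving out 1 library at a time gave 3474 to 4518, 0 to 51 and 4299 to 5200 genes, and 15 to 18, 2 to 10 and 13 to 16 lists. The M1 medians then ran from 0.23 to 0.36, -0.10 to 0.076 and 0.42 to 0.67, and the M2 medians from 0.08 to 0.49, 0.049 to 0.21 and 0.27 to 0.54. The test of the 3 groups gave 3900 to 4922 genes, 3104 to 3932 went the same way in both membrane groups, and 0 to 2 went opposite ways. The cause was not tested.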

Other observations

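Lists that camera did not call still held genes that changed in BMC against control. Rcan1 rose 3.67-fold and the calcium pump Atp2a3 rose 3.92-fold among 23 calcineurin and calcium response genes, of which 8 rose and 7 fell. The inflammasome sensor Nlrp3 rose 2.19-fold and Nek7, which binds it, fell by 0.54 log2, in a list where 4 of 12 rose and 4 fell. Of 18 interferon-stimulated genes 0 rose by edgeR and 4 fell, with Ifit2 3.07-fold lower (camera adjusted p = 0.103), and 8 fell in BMC+LIPUS against control. Among 17 mechanosensitive and calcium channels 3 rose and 6 fell, and the ATP-gated channel P2rx7 fell from 5.03 to 2.68 FPKM. Of 21 integrin and focal adhesion genes 6 rose and 2 fell, with the hyaluronan receptor Cd44 rising from 35.5 to 68.1 FPKM. Of 35 actin cytoskeleton genes 12 rose and 5 fell, and 16 rose and 6 fell adjusted over the list alone, with Actg1 rising from 150 to 235 FPKM. Of 15 osteoclast genes 7 rose and 4 fell, and 7 rose and 6 fell adjusted over the list alone, with carbonic anhydrase Car2 rising from 72.0 to 189 FPKM and Mitf from 18.7 to 35.8. Of 11 growth and angiogenic factors 4 rose and 4 fell, with Vegfa rising from 3.29 to 5.60 FPKM and Igf1 falling by 1.02 log2 in BMC+LIPUS against control. The 4 YAP/TAZ target genes above the filter (Amotl1, Ajuba, Lats2 and Nuak2) were not called in BMC against control, and Lats2 rose by 0.43 log2 in BMC+LIPUS against control (edgeR adjusted p = 0.0107).

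In metabolism and stress, Cpt1a, the carnitine transferase of fatty acid oxidation, fell from 6.30 to 3.05 FPKM in BMC, in a list where 2 of 20 rose and 6 fell. The cystine transporter Slc7a11 rose from 2.30 to 6.27 FPKM among 25 NRF2 and antioxidant genes, of which 6 rose and 4 fell. Sqstm1, an autophagy receptor, rose from 128 to 237 FPKM among 31 lysosome and autophagy genes, of which 8 rose and 8 fell, and 9 rose and 11 fell adjusted over the list alone. Of 23 sterol biosynthesis genes 6 rose and 3 fell, with Hsd17b7 rising by 0.37 log2. Of 14 metallothionein and metal transport genes 5 rose and 2 fell, with the iron reductase Steap3 falling by 1.01 log2. Of 22 unfolded protein response genes 5 rose and 1, Sdf2l1, fell, and Herpud1 rose by 0.40 log2. Of 19 macrophage identity genes 7 rose and 5 fell, with Irf8 rising by 0.51 log2 and the pore-forming Mpeg1 falling from 185 to 129 FPKM. Of 20 TCA cycle genes 3 rose and 3 fell, Idh2 by 0.32 log2. Of 43 nuclear oxidative phosphorylation genes 2 rose and 2 fell, and 0 adjusted over the list alone, and of 15 mitochondrially encoded genes 1 rose over all genes and 0 adjusted over the list alone. Median and mean differed in sign in the channel, calcineurin, growth factor, TCA, NRF2, metallothionein, lysosome and macrophage identity lists.

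The endotoxin gene test and the regroupings of libraries below were chosen after the result was seen, and the other tests were laid down before their values were computed. Within groups, the first component of the spread held 27.3% of it and had a Pearson's r of 0.994 with the score of Slc5a3, Akr1b3, Slc6a12 and Hspa4l, whose loadings ranked 21, 20, 73 and 24 of 12030 genes and which were chosen after the component was seen. Of these, Slc6a12, Akr1b3 and Hspa4l were called higher in BMC than in control, and all 4 in BMC+LIPUS against control. A different tonicity of the medium could raise them: 4 other tonicity genes, Slc6a6, Slc38a2, Nfat5 and Sgk1, had a median within-group r of 0.772 with the score (exact within-group permutation p = 0.0185), and 0.579 without BMC replicate 1 and BMC+LIPUS replicate 2. Adjusted over the 4 genes, this permutation test gave p = 0.0185 for Slc38a2 and 0.0370 for Nfat5. It gave 0.0741 for Slc6a6 and 0.120 for Sgk1, which had r = 0.473 at a mean of 1.22 FPKM. Slc6a6, however, fell by 0.18 log2 in BMC. Gene length bias was excluded, since the SD of the score was 1.00 times its size after a length trend was removed, and so was library depth as its whole cause, at r = -0.072, or -0.448 without the 2 libraries whose sizes lay farthest from the median.

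By fitted values, BMC+LIPUS lay further from control along the BMC change: 2716 of 4314 genes called in BMC against control had a fitted change in the same direction in BMC+LIPUS against BMC. The slope of the second change on the first over these genes was 0.067. The shared BMC libraries and the choice of called genes both push this slope down, so it does not give the size of the shift. BMC libraries shared by both contrasts would push the covariance of the changes down. With them shared, it was -0.0105 for the edgeR changes, against -0.0335 in simulations of unchanged groups, and 0.00819 for differences of mean log2 CPM. With these libraries divided between the contrasts, the smallest covariance of 6 divisions was 0.0108 and the largest 0.0486, at Pearson's r across genes of 0.087 and 0.333. With the osmotic score as a covariate the mean covariance was 0.853 times its size, and 0.845 to 1.32 when each library was left out, but the 2 largest covariances, 0.0486 and 0.0423, fell to 0.0224 and 0.0204. All 6 stayed above 0, at 0.0204 to 0.0312. However, the same fitted slope per gene corrected both contrasts, so its error can itself add to their covariance. What tonicity alone would leave was not simulated, so tonicity was not excluded as the whole cause or as a part of it. A stronger version of the membrane response under ultrasound could give this pattern, but so could any difference in culture between the groups. So could a chance difference between libraries, since regroupings were not scored for this pattern. Repeat cultures with and without ultrasound would be needed to separate these. A group with ultrasound and no membrane would be needed to tell a stronger membrane response from an effect of ultrasound alone.

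The rise of chemokine and NF-kB genes such as Cxcl2, Ccl3 and Traf1 on the membrane could come from bacterial endotoxin. Of 18 endotoxin response genes, 2 (Ptgs2 and Cxcl10) were called higher and Ifit2 lower, 4 were not called, and 11 were below the filter. A broad rise of these 18 genes was therefore not seen. The 18 genes were chosen after the result was seen, so this test cannot exclude endotoxin. With the osmotic score as a covariate, the median change of the 29 members was 1.13 times its size, so tonicity as the score measures it was excluded as the whole cause. With that covariate all 38 DNA replication genes were still called lower in BMC. A limulus assay of the medium on the membrane would test the endotoxin hypothesis directly.

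Regroupings asked whether chance could give these counts. The 6 libraries of a comparison have 10 divisions into 3 and 3, too few for a share under 0.05. In BMC against control 1 division, the real one, gave as many genes, 4339 against a highest other of 0, and 1 gave as many lists, 17 against 16. In BMC+LIPUS against control 1 gave as many genes, 5121 against 0, and 1 as many lists, 16 against 12. In BMC+LIPUS against BMC, 2 divisions gave at least the real 2 genes, with a highest other of 265, and 6 gave at least the real 5 lists, with a highest other of 13. The division with 265 genes set BMC replicate 3 with BMC+LIPUS replicates 1 and 3, the libraries with the highest osmotic scores. For the 3 groups, 1 of 100 drawn regroupings, the real one, gave 4919 genes and the highest other gave 4690. The 4 others that kept the controls together gave 4355 to 4690, and the 95 that did not gave 0 to 7. The regroupings that kept the controls together, the real one and 4 others of 100, rearranged only the BMC and BMC+LIPUS libraries. All of them hold the difference of the controls from the membrane groups. Their number is therefore not a share for chance in that difference. Regroupings that mixed controls with membrane libraries gave at most 7 genes, so the high counts went with keeping the controls apart. Chance was not excluded for the division into BMC and BMC+LIPUS. Regrouping libraries cannot show whether cultures differ by chance, since the labels do not say that the libraries were separate cultures.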
